A study of Rattus norvegicus with 4 samples.

How the data were processed

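The series holds 4 samples of hypothalamic total RNA from Wistar rats aged 4 months, 1 for each combination of prenatal group (control or FR30) and diet (standard or high-fat, HF). Groups were taken from the sample labels. RNA was extracted with Trizol, cleaned on columns and labelled with biotin for Illumina bead arrays, per the labels' protocols. Whether a sample is 1 animal, a pool or several arrays, and what the probe sequences and genome build are, is not given in the sources used here.

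The deposited tables came from GenomeStudio, per the submitters' processing notes, with no version given. The non-normalized table holds the authors' average bead intensity per probe, on a linear scale, and a deposited detection p-value for each. The normalized table holds the authors' intensity after a normalization whose method is not given in the sources used here, a detection p-value and, per the file headers, an SD. The normalized medians lie between 181.0 and 181.2 and are nearly equal. A further table of deposited values was identical to these normalized intensities (largest difference 0), so its scale is linear and it was not centred. The variance of the log squared SD at like signal was between 1.70 and 1.75, near the 1.64 of an SD over 3 values with 2 degrees of freedom, and the log of SD over signal of 1 group correlated with that of another across probes at no more than 0.0634. Because neither the number nor the kind of values behind the SD is given, no p-value was computed from it. Median non-normalized signals were 190, 173, 169 and 177 in control standard, control HF, FR30 standard and FR30 HF, and the steps of the detection p imply 825 negative control probes. The number of samples, 1 per group, limits the precision.

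From the non-normalized intensities, log2 values were computed with limma 3.58.1 in R 4.3.3 by neqc, which corrects the background from the detection p-values, adds an offset of 16 and applies quantile normalization. Each gene was represented by the probe with the highest mean over the 4 samples. Of the genes named below, Akr1c12, Aurkb, Plekhh1 and Zyg11b also had further probes, which were not detected in any sample. The values of these genes therefore rest on the probe used alone. Symbols in the files were matched to RefSeq gene names: 10291 probes held a current symbol, 4966 an older symbol, 1642 a gene number, 5495 a symbol without a match, which was kept as the file gives it, 117 no symbol and 12 a date in its place. This gave 21406 genes. Probes without a symbol were left out, and none of the detected ones was used for a gene. No coordinates are given. A result on a gene withheld for evaluation is not reported here.

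With 1 sample per group, the 4 pairwise comparisons were described by size: genes detected at p under 0.01 in both samples whose difference was at least 1.5-fold, with no test. A gene detected in only 1 of the 2 samples has a bound, written as at least N-fold. Prenatal group and diet together were tested with an additive limma fit on genes detected in all samples, with Benjamini-Hochberg adjustment and a prior of 3.79 degrees of freedom. The genes named are the 8 furthest in each direction of each comparison among named genes, the 5 furthest for the difference of diet differences and for genes past 1.5-fold in the same direction in both pairs, up to 4 members past 1.5-fold of each gene list and comparison, and a fixed set of well-known hypothalamic genes. This rule and 22 gene lists of pathways, cell types and neighbouring tissues were fixed before the data were examined. A list is described by its median and the percentile of that median among 10000 random lists of the same size drawn from the same expression deciles; lists share genes. Marker lists for midbrain dopamine neurons, serotonin neurons, reticulocytes, thalamus and telencephalon were written later, each before it was tested; the serotonin list had only 2 detected genes and no median. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

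The steps were tested on simulated data with 200 changed genes among 10109. For FR30 on standard diet, 52% of genes simulated at 1.5-fold passed the size threshold and 89% were called by the additive fit. At 2-fold these shares were 100% and 99%. Of the unchanged genes in the same simulation, between 0.343% and 0.404% passed the size threshold. Between 0.101% and 0.242% of them were called by the fit. The simulated noise was drawn from the prior of the fit, and no interaction was planted. These shares therefore do not tell how many real changes the fit finds. In the real data, Amy1 (1.15) and Sorbs2 (-1.14) lay past 2-fold in the fit and were not called. For 241 genes with 2 detected probes, the differences of the probes were correlated across genes. Pearson's r was 0.450 and 0.820 for diet in control and FR30 offspring and 0.657 and 0.432 for FR30 on standard and HF diet. Spearman's rho was lower, at 0.309, 0.386, 0.189 and 0.260 in the same order. Only 1 or 2 of the 241 genes passed 1.5-fold in each comparison. Rps9, whose probes showed 2.01 and 4.54 for diet in FR30 offspring, was among the 241. Alternatives covered the background correction, the normalization, the authors' table, the detection filter, the probe per gene, the size threshold and the prior variance.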

Results

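Gene expression was measured with Illumina rat bead arrays, on which each probe is a short DNA attached to beads, in total RNA of isolated hypothalami from male Wistar rats aged 4 months. The rats were control offspring or FR30 offspring, which were undernourished before birth, and each kind had eaten a standard or a high-fat (HF) diet. Each of the 4 groups was represented by 1 sample, so the differences between groups had no replicate check. The deposited table gave an SD beside each signal, printed below as ± deposited SD, without saying what it was taken over or how many values it held. Its median was between 3.20% and 3.41% of the signal in the 4 groups. The 4 samples held 22523 probes each, of which 10776 were detected in control offspring on standard diet, 11122 in control offspring on HF diet, 10579 in FR30 offspring on standard diet and 10712 in FR30 offspring on HF diet, at a detection p under 0.01. Differences are given on the log2 scale after background correction and quantile normalization. Genes named as examples of a list, without having passed 1.5-fold, were chosen after their values were seen.

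Of the hypothalamic peptide genes best known for feeding, Agrp, Npy, Pmch and Hcrt differed little between the 4 groups and Pomc differed more. Agrp, the peptide of the appetite-promoting neurons of the arcuate nucleus, had normalized signals of 714 ± 9.71 (deposited SD) in control offspring on standard diet, 799 ± 3.50 on HF diet, 747 ± 27.7 in FR30 offspring on standard diet and 816 ± 18.3 on HF diet. Npy, which is made by the same neurons, differed by 0.09 between HF and standard diet in control offspring and by 0.12 in FR30 offspring. Pomc, the precursor of the satiety peptide alpha-MSH, was higher on HF diet by 0.24 in control offspring and by 0.55 in FR30 offspring, where its signal was 2318 ± 113 on standard diet and 3497 ± 199 on HF diet. Between FR30 and control offspring, Pomc differed by 0.21 on standard diet and by 0.53 on HF diet. Pmch, Hcrt and Mc4r differed by between -0.08 and 0.22 in the 4 comparisons. Cartpt was lower in FR30 offspring by a log2 difference of -0.15 on standard diet and -0.20 on HF diet, and Sst by -0.32 and -0.16. Crh, which drives the stress axis, showed -0.28 on standard diet and -0.10 on HF diet, and Avp -0.14 and -0.12. For Oxt the HF difference was -0.42 in control offspring and -0.07 in FR30 offspring, and for Trh it was -0.11 and 0.18. Nr3c1, the glucocorticoid receptor, differed by 0.19 between FR30 and control offspring on standard diet and by 0.08 on HF diet. The leptin receptor gene Lepr was not detected in any of the 4 samples. None of these genes reached 1.5-fold, a log2 difference of 0.58, in any of the 4 comparisons, except that Pomc on HF against standard diet in FR30 offspring reached 0.59 in the authors' normalized table.

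**Figure D1:**
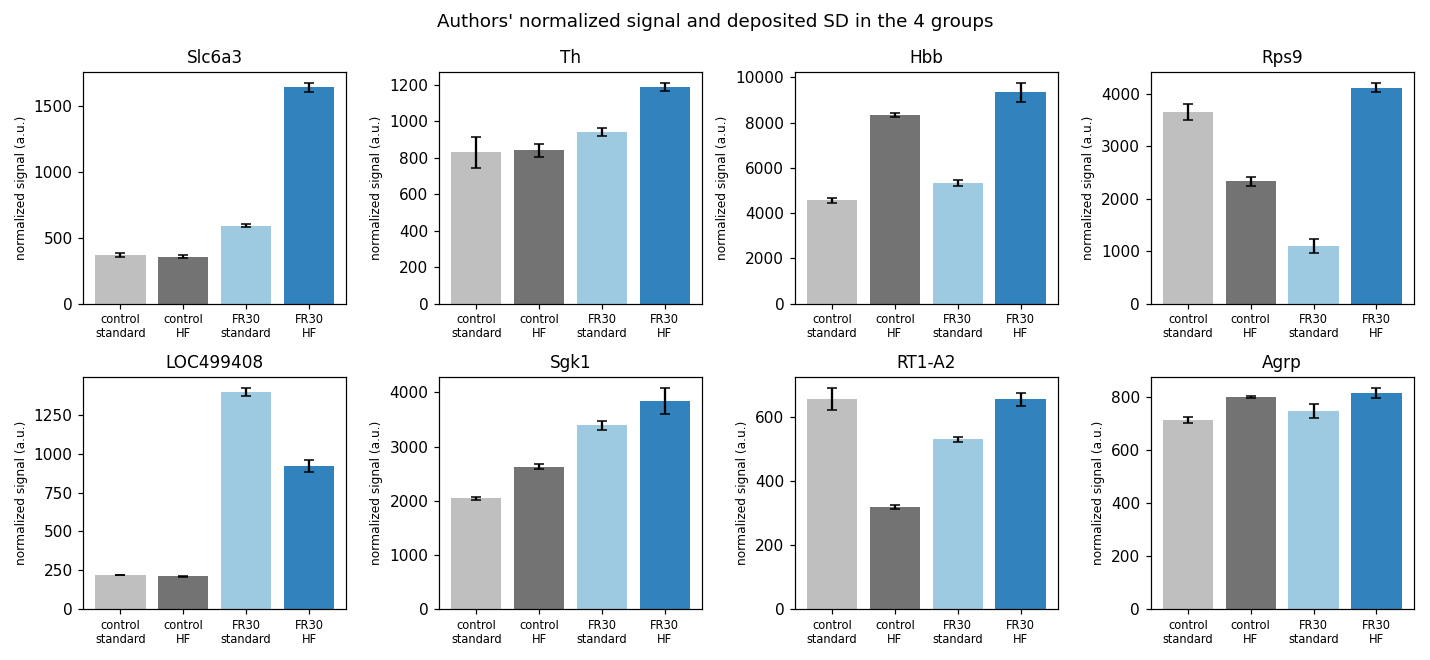
Bars show the authors' normalized signal of 8 genes in the 4 groups in arbitrary units, and whiskers the deposited SD, for which the number of values is not given. Slc6a3 stands at 1642 in FR30 offspring on HF diet and at 357 in control offspring on HF diet, while Agrp lies between 714 and 816.

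The first comparison asked what the HF diet was accompanied by in control offspring. The beta-globin gene Hbb was higher on HF diet by 0.89, with a signal of 4559 ± 94.8 (deposited SD) on standard diet and 8350 ± 85.5 on HF diet. Higher values were also found for Tmem179 (1.32), the cystine transporter subunit Slc3a1 (1.16), the lipoxygenase gene Alox15 (0.80), Depp1 (0.69), Pkib (0.66), the zinc transporter Slc39a12 (0.65) and the class I histocompatibility gene RT1-A3 (0.65). Another class I gene, RT1-A2, had the lowest value among genes detected in both samples, -1.49, with a signal of 655 ± 34.1 on standard diet and 319 ± 5.80 on HF diet. Variants under the probes of these class I genes were not checked, and RT1-A2 and RT1-A3 differed in opposite directions. It was followed by the aldo-keto reductase Akr1c12 (-1.09), the integrin Itga1 (-0.97), Commd6 (-0.96), the neuromedin B receptor Nmbr (-0.93), the synaptic endocytosis gene Pacsin1 (-0.91), the cyclic AMP phosphodiesterase Pde4d (-0.90) and Adgrb1 (-0.89). In all, 61 of 10407 genes detected in both samples differed by 1.5-fold or more, 15 higher and 46 lower on HF diet, and 57 of them had deposited signals more than 2 SD apart on each side. Of all 10407 genes, 1147 were that far apart. A 1.5-fold difference mostly exceeds this gap by construction, because the median SD was a few percent of the signal. The same holds for such counts in the other comparisons.

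Among the 22 gene lists, 2 stood higher and 4 lower than all but 2.5% of random lists matched on expression. Of 25 detected genes of inflammation and microglia, 20 were higher on HF diet and 5 lower, with a median of 0.12 that 0 of 10000 random lists reached. Cd14 (0.38), Nfkbia (0.37), the integrin Itgam (0.31) and Cd68 (0.30) were among the higher ones, none past 1.5-fold, whereas the class II histocompatibility genes RT1-Db1 (-0.32) and RT1-Ba (-0.30) were lower. Of 34 proteasome genes 26 were higher, with a median of 0.07 and Psmd5 (0.47) the furthest. Of 23 leptin and insulin signalling genes 15 were lower, with a median of -0.08, among them Pik3cb (-0.30) and Gsk3b (-0.28). Of 17 genes of endothelium, meninges and blood 12 were lower, with a median of -0.07, among them the matrix genes Ogn (-0.55) and Col3a1 (-0.53), while Hbb was higher. Of 37 genes of GABA and glutamate transmission 21 were lower, with a median of -0.05, and the NMDA receptor subunit Grin2a passed 1.5-fold at -0.61.

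Markers of thalamus moved with this comparison. Of 21 detected marker genes of thalamus, striatum and cortex 14 were lower on HF diet, with a median of -0.16 that 0 of 10000 random lists reached. Ramp3 (-0.70) and Prkcd (-0.60) were among those past 1.5-fold. Outside this list, Rora (-0.84), a clock gene, and Enpp6 (-0.72), a gene of early oligodendrocytes, passed it too. A further list of thalamus markers, written after some values had been seen, had a median of -0.39 with 13 of 14 genes lower, while a further list of telencephalon markers had one of -0.03, with 6 higher and 9 lower, inside the range of random lists. The reticulocyte list, written at the same time, had a median of 0.14 with 5 of 6 genes higher. Ttr and Prl, which mark choroid plexus and pituitary, were detected on standard diet and not on HF diet, at least 7.90-fold and at least 12.7-fold lower on HF diet; these bounds set the brighter value against the lowest detected signal of the other sample or the dim probe's own, whichever was higher. With the authors' normalized signals, which keep the background, 16 genes passed 1.5-fold, 7 higher and 9 lower.

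In FR30 offspring the HF diet was accompanied by higher values of Slc6a3, the dopamine transporter, by 1.68, with a signal of 593 ± 13.7 (deposited SD) on standard diet and 1642 ± 33.7 on HF diet. Ttr, the thyroid hormone carrier of the choroid plexus, was higher by 3.91, the alpha-globin gene Hba-a3 by 2.03, the ribosomal protein gene Rps9 by 2.01, Rnf113a2 by 1.26, the m6A reader Ythdf2 by 1.03, the efflux transporter Abcg2 by 0.91 and Tmem243 by 0.86. Hbb was higher by 0.86, close to its difference in control offspring, and the somatostatin receptor gene Sstr1 by 0.76. The largest lower value belonged to Commd6 (-1.71), followed by C10h17orf75 (-1.15), Zyg11b (-1.10), the mitotic kinase Aurkb (-1.01), the transcription factor Zic2 (-0.98), Tnrc6a (-0.83), Prl (-0.75) and Mybpc1 (-0.61). There were 33 genes past 1.5-fold among 10186, 20 higher and 13 lower, of which 31 had deposited signals more than 2 SD apart on each side. These were 0.324% of the genes. Between 0.343% and 0.404% of unchanged genes passed 1.5-fold in the simulated data, where all samples had the same noise. The count alone therefore does not set these genes apart from simulated noise.

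Of 23 detected oligodendrocyte and myelin genes, 21 were higher on HF diet in FR30 offspring, with a median of 0.09 that 0 of 10000 random lists reached and Mag (0.26), Qdpr (0.17) and Cryab (0.15) among them. Of 76 ribosomal protein genes 59 were higher, with a median of 0.06. The medians were 0.05 for 18 genes of the glucocorticoid and HPA axis, 0.05 for 19 genes of the thyroid, growth and reproductive axes, of which 10 were higher and 9 lower, and 0.03 for 39 genes of fatty acid metabolism, each exceeded by fewer than 2.5% of random lists. Lower than all but 2.5% of random lists were GABA and glutamate transmission, where 29 of 35 genes were lower with a median of -0.07, including Gabbr1 (-0.39) and Grm2 (-0.39), and the markers of thalamus, striatum and cortex, with a median of -0.07. The list of midbrain dopamine neuron markers, written after Slc6a3 had been seen, had a median of 0.16 with 9 of 10 genes higher, and the reticulocyte list a median of 0.12 with 5 of 6 genes higher. With the authors' normalized signals 19 genes passed 1.5-fold, and with a detection p under 0.05 there were 50.

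The prenatal comparison on standard diet asked how FR30 offspring differed from control offspring without the HF challenge. The salivary amylase gene Amy1 was higher in FR30 offspring by 1.25, with a signal of 380 ± 4.26 (deposited SD) against 237 ± 11.3 in control offspring. Zic2 was higher by 1.03, Slc6a3 by 0.97, Zyg11b by 0.93, Zcchc9 by 0.90, Slc3a1 by 0.89, Plekhh1 by 0.87 and the hydroxylase gene Kdm8 by 0.83. The serum- and glucocorticoid-induced kinase gene Sgk1 was higher by 0.71, at 3392 ± 88.1 against 2045 ± 28.2. Lower in FR30 offspring were Ttr (-2.38), Rps9 (-1.84), Prl (-1.79), Pde4d (-0.96), Hycc2 (-0.93), Sorbs2 (-0.92), Ttc30a1 (-0.87) and the sterol desaturase gene Sc5d (-0.80) of cholesterol synthesis. A dimmer Rps9 probe showed -4.28. Among list members past 1.5-fold, the bicarbonate transporter Slc4a4 (-0.79), the GABA receptor subunit Gabrb2 (-0.74), Sstr1 (-0.73), the GABA-synthesising enzyme gene Gad2 (-0.60), the relaxin-3 receptor Rxfp3 (-0.59) and the DNA demethylase gene Tet2 (-0.59) were lower, and the glutamate receptor Grm2 (0.81) was higher. The unnamed locus LOC499408, named here after its value was seen, stood furthest above control at 3.85, with a signal of 1399 ± 25.3 against 221 ± 0.981. Of 10193 genes 79 passed 1.5-fold, 24 higher and 55 lower, and 74 of them had deposited signals more than 2 SD apart on each side. These were 0.775% of the genes, while between 0.343% and 0.404% of unchanged genes passed 1.5-fold in simulated data whose noise was set by the interaction of prenatal group and diet.

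Of 18 detected genes of the glucocorticoid and HPA axis, 12 were higher in FR30 offspring on standard diet, with a median of 0.09 that 69 of 10000 random lists reached. Besides Sgk1 they included the glucocorticoid-responsive genes Per1 (0.52), Nfkbia (0.43), Dusp1 (0.37) and Tsc22d3 (0.22). Of 24 immediate early genes, which neuronal activity and stress induce, 19 were higher, with a median of 0.10 and Klf2 (0.54) and Fos (0.43) at the top. Of 26 hypothalamic nucleus markers 15 were lower, with a median of -0.09 that 0 of 10000 random lists reached, including Vip (-0.31) and Six6 (-0.31). The median of 19 genes of the thyroid, growth and reproductive axes was -0.13, with 12 lower, among them the thyroid hormone receptor Thrb (-0.44). Ribosomal protein genes had a median of -0.01 and anterior pituitary genes of -0.08, both lower than all but 2.5% of random lists. Neither stayed there without 1 gene: the ribosomal list without Rps9 had a median of -0.0093 at percentile 3.74, and the pituitary list without Prl one of -0.04 at percentile 10.6, with 5 genes higher and 5 lower. The median of the midbrain dopamine markers was 0.10, and that of the second list of thalamus markers -0.03. With the authors' normalized signals 28 genes passed 1.5-fold, 12 higher and 16 lower.

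On HF diet the same prenatal contrast gave its highest value among named genes detected in both samples for Slc6a3, which was higher in FR30 offspring by 2.72. The unnamed locus LOC499408 lay above it, at 3.34. Hba-a3 was higher by 2.19, RT1-A2 by 1.49, the organic cation transporter Slc22a2 by 1.17, the cytochrome P450 gene Cyp4b1 by 1.10, Zcchc9 by 1.10, Amy1 by 1.04 and the efflux transporter Slc47a1 by 0.98. Th, the enzyme that limits dopamine synthesis, was higher by 0.60, at 1190 ± 21.6 (deposited SD) against 841 ± 33.4, and the growth factor binding protein gene Igfbp2 by 0.71. Lower values belonged to Aurkb (-1.97, at 567 ± 30.6 against 1855 ± 35.2), Sorbs2 (-1.36), Tmem179 (-1.23), RT1-A3 (-1.17), C10h17orf75 (-1.17), the interferon-inducible GTPase Ifi47 (-0.94), Tnrc6a (-0.92) and Fam151b (-0.84). Another Aurkb probe was not detected in any sample, so the Aurkb value rests on the brighter probe alone. Further list members past 1.5-fold were Prkcd (0.66), Sult1a1 (0.59), Ogn (0.59) and Rps16 (-0.59). Of 10356 genes 83 passed 1.5-fold, 57 higher and 26 lower, and 78 had deposited signals more than 2 SD apart on each side.

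Oligodendrocyte and myelin genes stood apart here, with 22 of 24 higher in FR30 offspring and a median of 0.15 that 0 of 10000 random lists reached. Mag (0.37), Cryab (0.37), Opalin (0.32) and Sox10 (0.26) were among them. The FR30 median of this list on standard diet was 0.04, inside the range of random lists. On HF diet both samples stood apart from the mean of the other 3. FR30 offspring deviated by 0.15 and control offspring by -0.09, the latter with 21 of 23 genes lower. The glucocorticoid and HPA axis had 15 of 18 genes higher and a median of 0.10, with Sgk1 at 0.51 and Nr3c2, the mineralocorticoid receptor, at 0.25. Of 60 genes of oxidative phosphorylation 47 were higher, with a median of 0.05, and of 78 ribosomal protein genes 48, with a median of 0.03. Immediate early genes had a median of 0.08, with 15 of 24 higher. Genes of GABA and glutamate transmission had a median of -0.10 with 25 of 35 lower, among them Gad2 (-0.45) and Slc6a11 (-0.42), and hypothalamic nucleus markers one of -0.06, with Isl1 at -0.39 and Nkx2-1 at -0.34. The anterior pituitary list had a median of 0.23 over 9 genes, with 5 higher and 4 lower. Markers of other tissue moved with this comparison: the midbrain dopamine list had a median of 0.29, the second list of thalamus markers one of 0.25 and the reticulocyte list one of 0.10. Ttr and Prl were not detected in control offspring on HF diet and were at least 22.7-fold and at least 2.18-fold higher in FR30 offspring. With the authors' normalized signals 26 genes passed 1.5-fold.

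**Figure D2:**
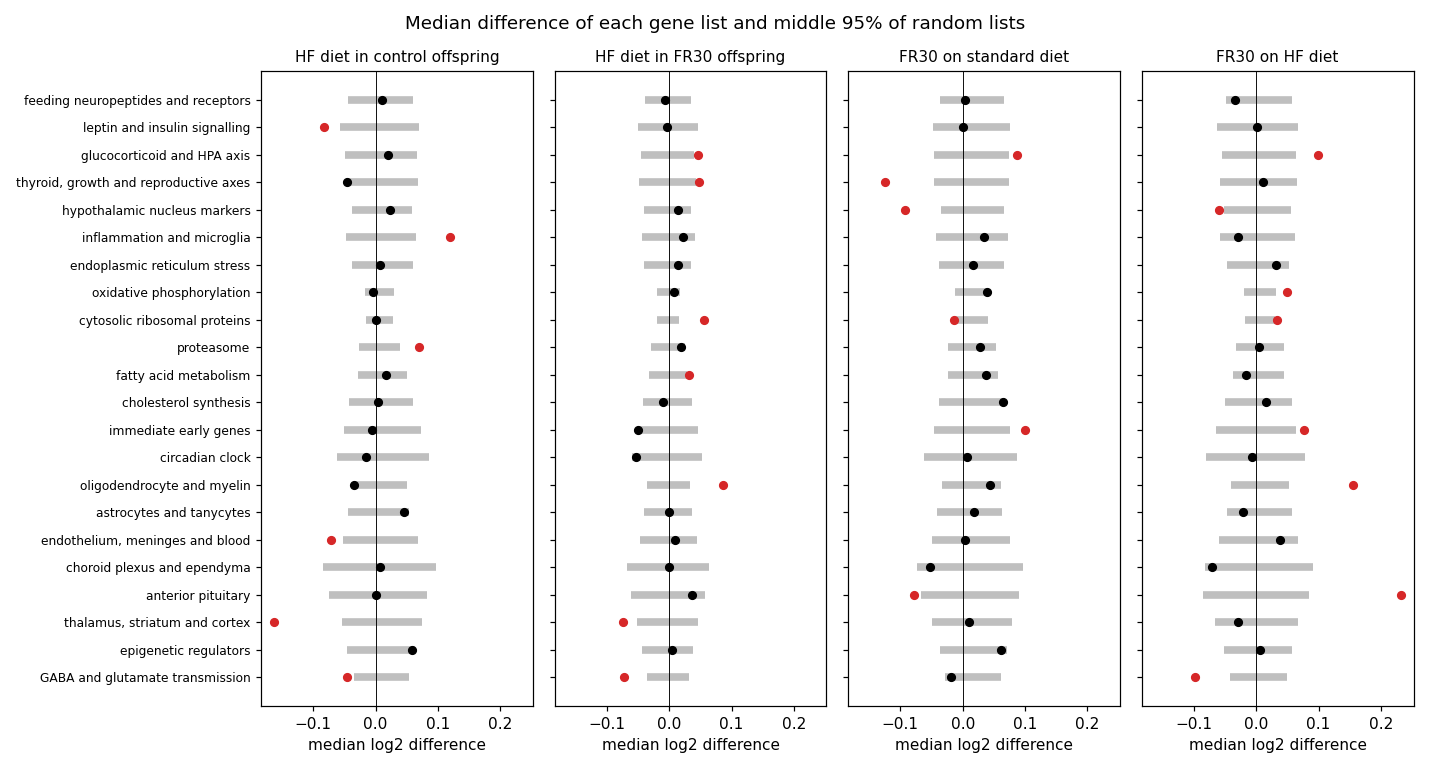
Points give the median log2 difference of each of the 22 gene lists in the 4 comparisons, and grey bars the range of 10000 random lists matched on size and expression without the 2.5% at each end, with points outside the bar in red. Oligodendrocyte and myelin genes reach 0.15 in FR30 offspring on HF diet, and the thalamus, striatum and cortex list -0.16 for HF diet in control offspring.

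The diet difference itself differed between FR30 and control offspring by 1.5-fold or more for 125 of 10109 genes detected in all samples, being higher in FR30 offspring for 67 and lower for 58. Rps9 had the largest such gap among named genes, 2.62, since it was lower on HF diet in control offspring (-0.62) and higher in FR30 offspring (2.01). RT1-A2 followed at 1.88, Slc6a3 at 1.76, Rnf113a2 at 1.49 and Ythdf2 at 1.35. On the other side stood Aurkb (-1.24), Zic2 (-1.22), RT1-A3 (-1.21), C10h17orf75 (-1.20) and Ifi47 (-1.08). With the interaction tested by limma beside prenatal group, and diet as the error, 0 genes were called (337 at an unadjusted p under 0.05), and beside diet, with prenatal group as the error, 0 genes (192). These fits were added after seeing the data, and the 4 samples leave no error of their own once both factors and the interaction are fitted. The authors' normalized signals gave 30 such genes.

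Across the same 10109 genes, the FR30 difference on standard diet correlated with that on HF diet with a Pearson's r of 0.334 and a Spearman's rho of 0.296, and the diet difference in control offspring with that in FR30 offspring with 0.0975 and 0.119. Neither pair of differences shares a sample, and genes are not independent replicates. FR30 offspring differed by 1.5-fold or more in the same direction on both diets for 11 genes, where independent lists would share 0.257, and in opposite directions for 3, where they would share 0.329. Slc6a3, Amy1, Zcchc9, Slc47a1 and H2az2l3 were higher on both diets, and so was LOC499408, at 3.85 and 3.34. Aurkb, Sorbs2, Gnpda2 and Pxmp4 were lower on both, as was the unnamed locus LOC500663, at -1.13 and -0.93. Gnpda2, an enzyme gene of hexosamine breakdown, had values of -0.77 and -0.68, and Pxmp4, a peroxisomal membrane protein gene, -0.69 and -0.75. The diet difference passed 1.5-fold in the same direction in both kinds of offspring for 3 genes, where independent lists would share 0.0742: Hbb, the globin-like locus MGC72973 (0.81 and 0.85) and Commd6. It passed 1.5-fold in opposite directions for 2, where they would share 0.0920: Rps9 and the unnamed locus RGD1564649.

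**Figure D3:**
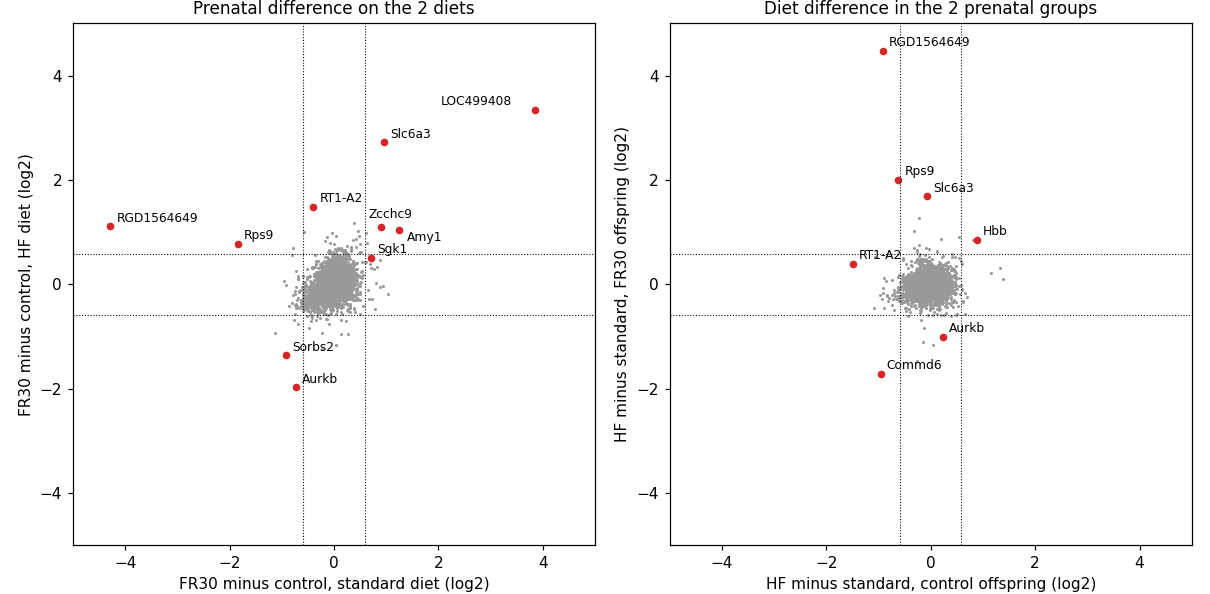
Each point is 1 of the 10109 genes detected in all 4 samples. The left panel sets the FR30 minus control log2 difference on HF diet against that on standard diet, the right panel the HF minus standard difference in FR30 against control offspring, and dotted lines mark 1.5-fold. LOC499408 lies at 3.85 and 3.34 in the left panel and Hbb at 0.89 and 0.86 in the right.

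An additive fit of prenatal group and diet, in which their interaction serves as the error with 1 residual degree of freedom per gene, called 1 gene for FR30 by limma at an adjusted p under 0.05. This was LOC499408, higher in FR30 offspring by 3.60 (SE 0.130, limma adjusted p = 0.0180), with the same direction on 2 of 2 diets. It rests on 1 probe, under which a sequence variant was not checked because probe sequences were not used here. For diet limma called 0 genes, and its lowest adjusted p was 0.213. At an unadjusted p under 0.05 there were 1274 genes for FR30 and 717 for diet. Averaged over both diets, 16 of 18 genes of the glucocorticoid and HPA axis were higher in FR30 offspring, with a median of 0.14 that 0 of 10000 random lists reached. Markers of other cells and tissues were higher in the same average, with a median of 0.11 for oligodendrocyte and myelin genes, 0.14 for the midbrain dopamine list and 0.09 for the second list of thalamus markers. On standard diet alone these lists had medians of 0.04, 0.10 and -0.03, each inside the range of random lists. On HF diet they had 0.15, 0.29 and 0.25. In the average, immediate early genes had a median of 0.10, with 21 of 24 higher, and hypothalamic nucleus markers one of -0.07, with 15 of 25 lower. Against the mean of the other 3 samples, the glucocorticoid list had a median of -0.14 in control offspring on standard diet, -0.06 in control offspring on HF diet, -0.0030 in FR30 offspring on standard diet and 0.12 in FR30 offspring on HF diet. With a prior variance that followed the signal the FR30 count was 199 genes, 47 higher and 152 lower, and the diet count 3, and with the authors' normalized signals the counts were 70 and 3. With the interaction kept as a term and diet left as the error, the FR30 count was 0, so the call of LOC499408 was not kept, or 2 with the prior that followed the signal.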

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

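Among the tests below, only those of the second thalamus and telencephalon lists in the control sample on standard diet were set before their values were seen. Rps9, Rnf113a2 and the unnamed locus RGD1564649 stood out because their differences went opposite ways on the 2 sides of a contrast, past 1.5-fold in each. For these genes the difference between groups was not tested with replicates; with diet or prenatal group as the error, limma called 0 genes for the interaction (337 and 192 at an unadjusted p under 0.05). Rps9 was higher on HF diet by 2.01 in FR30 offspring and lower (-0.62) in control offspring, and relative to control it was higher in FR30 offspring by 0.78 on HF diet and lower (-1.84) on standard diet. RGD1564649 followed the same order, at 4.47 and -0.92 for diet and 1.11 and -4.28 for FR30. Rnf113a2 was higher in FR30 offspring by 0.70 on HF diet and lower (-0.79) on standard diet.

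A sequence variant under only 1 of the Rps9 probes is argued against, since both probes of Rps9 were lower in FR30 offspring on standard diet, at -1.84 and -4.28. A variant that both probes cover was not checked, because probe sequences were not used here. The sizes also differed between the probes, at 2.01 and 4.54 for diet in FR30 offspring. A lower level of ribosomal protein transcripts as a class is argued against by the median of -0.0093 over the other 75 ribosomal protein genes. The RGD1564649 probe may report the same transcript as the dimmer Rps9 probe, because their 4 differences lay within 0.0933 of each other. A genotype shared by the animals of 1 group cannot be told apart from regulation: the deposited SD of the brighter probe in that group was 12.4% of its signal, at the 99.9th percentile, but what the SD was taken over is not given. Undernutrition before birth stays open as a biological explanation and was not tested.

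Slc6a3, the dopamine transporter, was 2.72 higher in FR30 than in control offspring on HF diet. The signals lay 29.3 times the sum of their deposited SDs apart, but measurement noise cannot be told apart from a difference between groups with a gene picked for its size and an SD over values that are not given. Midbrain dopamine tissue in that sample is a candidate source: 9 other detected genes of a midbrain dopamine list had a median of 0.24, at the 99.99th percentile, with Th at 0.60, Sncg at 0.62 and Aldh1a1 at 0.38 (signal 4002 against 3061), while Calb1, the brightest of the list, was at -0.05 (9396 against 9655), Gch1 at -0.04 and Nr4a2 at -0.06. Of the 18 members 8 were not detected in that sample, among them Ddc (signal 150), Pitx3, Lmx1a and En2, while the 10 detected ones were also detected in both control samples and 5 members are in other lists. Sncg was nearly as high in FR30 offspring on standard diet (signal 632 against 665 on HF diet), where it lay 0.51 above control. Aldh1a1 also lay above control on standard diet, by 0.21. Sncg therefore does not single out the HF sample, and Aldh1a1 does so only in part. Between HF and standard diet in FR30 offspring, the 9 genes had a median of 0.14, with 8 higher and 1 lower. Regulation of Slc6a3 by prenatal group and diet stays open and was not tested.

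Thalamus markers differed between the 2 control samples (-0.39 on HF diet), and telencephalon markers did not stand apart there (-0.03, 6 higher and 9 lower). In the control sample on standard diet the second thalamus list deviated from the other 3 samples by 0.20 and the second telencephalon list by 0.081, higher than all but 2.5% of random lists. More of either tissue in that sample cannot be told apart from less in others, because FR30 offspring on standard diet differed from it by medians of -0.03 and -0.02, a comparison added after the values of each sample were seen, and its hypothalamic nucleus markers, at 0.00061, did not decide whether it held less hypothalamus; those markers deviated by 0.08 in the control sample on HF diet (17 of 25 higher) and by -0.06 in FR30 offspring on standard diet (20 of 25 lower). Less thalamic tissue in the control sample on HF diet is a candidate explanation: there the thalamus list deviated by -0.32, with 13 of 13 genes detected in all 4 samples lower, among them the bright genes Kcnc2 (7905 against 9325 on standard diet) and Ntng1 (2455 against 3300). Tnnt1, left out because it was not detected in FR30 offspring, went the other way. It was higher by 0.56 on HF than on standard diet in control offspring (signal 219 against 192). Of the 18 thalamus markers 14 were detected in both control samples, without the 2 that other lists hold the deviation was again -0.32, and a diet effect on these genes stays open and was not tested.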

How the results depend on the processing

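Comparing 2 SD intervals, leaving out genes past 2-fold and keeping the interaction as a term were chosen after seeing the data. No direction of a named gene past 1.5-fold or of a list outside the random range reversed under the alternatives run on it, but many sizes moved. No paired analysis was possible because each group has 1 sample, and for the same reason no sample could be left out. Counts past 1.5-fold are given in the order diet in control, diet in FR30, FR30 on standard diet, FR30 on HF diet and difference of diet differences, against 61, 33, 79, 83 and 125. With no background correction they were 15, 19, 27, 25 and 32 (6 higher and 9 lower for diet in control, 12 and 15 for FR30 on standard diet), with normexp and an offset of 50 17, 20, 34, 35 and 40 (6 and 11, 14 and 20), and with the authors' table, to which the further deposited table is identical, 16, 19, 28, 26 and 30. Background left in the signal shrinks ratios by construction. At 2-fold they were 7, 12, 8, 17 and 19. A detection p under 0.05 gave 50 for diet in FR30, and no filter 60, with 221 for the difference of differences. The r of the FR30 differences was 0.370, 0.362 and 0.375 in the first 3 settings, 0.260 at a detection p under 0.05 and 0.193 with no filter; the r of the diet differences was 0.0424 and 0.0227 in the last 2, and 0.134 without genes past 2-fold. FR30 calls of the additive fit were 171, 132 and 70 in the first 3 settings and 199 with a trended prior, with 3 diet calls in each; with the interaction as the second term they were 0, or 2 with a trended prior. The cause was not tested for the correlations and calls. Of 298 values of named genes, 57 no longer passed 1.5-fold in the authors' table and 2 passed it with median scaling, which moved 31 of 88 list medians by more than the SD of random lists. The 298 include values that never passed 1.5-fold, such as those of Agrp. The share lost among values that had passed it was therefore larger than 57 in 298. The largest shift of the median of all genes was 0.02. Signal over background limits dim genes. The median signal in control offspring on standard diet was 190, against 144 for the dimmest undetected probes, those with the highest detection p-values.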

Other observations

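The reticulocyte list, with and without Hbb, was chosen after seeing the data, while the other lists here were fixed in advance. Globin genes were higher on HF diet in both kinds of offspring. Hba-a2, an alpha-globin gene, was higher by 0.55 in control and by 0.51 in FR30 offspring, beside 0.89 and 0.86 for Hbb. Without Hbb the reticulocyte list had a median of 0.13 for diet in control offspring and 0.09 in FR30 offspring, with 4 of 5 genes higher in each. Hba-a3 was not detected in control offspring on standard diet, and Alas2, the first enzyme of haem synthesis in red cell precursors, was not detected in both samples of any comparison.

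The choroid plexus list, to which Ttr did not contribute because it was not detected in control offspring on HF diet, had a median of -0.07 in FR30 offspring on HF diet against control, with 5 of 14 genes higher, while Sostdc1, another choroid plexus gene, was detected in FR30 offspring on HF diet at least 2.61-fold above control. Lhb, a gonadotropin subunit gene of the pituitary, was at least 1.63-fold lower on HF diet in control offspring. The unnamed locus LOC499823, chosen after its values were seen, had signals of 4806 and 11677 in control offspring on standard and HF diet and of 8167 and 8810 in FR30 offspring. Averaged over both kinds of offspring, the HF diet went with a median of -0.11 in the list of thalamus, striatum and cortex. It went with -0.08 in that of GABA and glutamate transmission and with 0.07 in that of inflammation and microglia. In FR30 offspring alone, the inflammation and microglia list had a median of 0.02 with 15 of 24 genes higher, at percentile 85.1. Also outside the random range in the average was the glucocorticoid and HPA axis, with a median of 0.06 and 14 of 18 genes higher. So were the lists of proteasome (0.05), ribosomal protein genes (0.04) and endothelium, meninges and blood (-0.07).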
